A study of Sus scrofa with 4 samples.

How the data were processed

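Small RNA libraries of the hippocampus of newborn Rongchang piglets, a Chinese pig breed, were sequenced on an Illumina HiSeq instrument. Per the labels' protocols, 8 littermates (4 females and 4 males) were divided into a control group of 4 and an oxidative stress group of 4. The second group received 200 mg of iron dextran, an injectable iron-sugar complex, into muscle on days 3 and 4 after birth. Tissue of the ventral and of the dorsal hippocampus was mixed within each group before RNA extraction, so each combination of region and treatment is 1 pooled library and there are 4 libraries. No group has a replicate, and the spread between piglets was not measured. The mixing step is read from a brief protocol text, which does not say how many piglets entered each pool.

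The submitters' processing notes name cutadapt 1.2.2, a read trimmer, and the pig genome builds Sscrofa 10.2 and susScr 3. The aligner, the quantifier and the miRNA database release are not given in the sources used here. The 3 deposited tables hold annotated pig miRNAs (326 rows), predicted miRNAs (1052 mature and star rows) and conserved miRNA sequences (2791 rows, 161 of them without a family name). The authors deposited reads for each library, per the file headers, and these are estimated counts, since many values are fractions. How the authors divided reads is not given in the sources used here. Between 75.8% and 77.0% of the cells per library in the annotated table are exactly whole (a tolerance of 0), cells of 0 included. Reads were rounded to whole numbers before use. The table of annotated miRNAs also holds RPM values, per the file headers. The divisor behind the authors' RPM was between 15748224 and 20347956 reads, within 0.1% of the sum of all annotated and predicted rows. That sum counts the reads of some miRNAs more than once: miR-9 and miR-218 each stand in 3 rows, and miR-490 in 2, with the full reads in each. Rows with the same precursors and reads within 0.1% of each other in every library were therefore merged, which left 321 annotated miRNAs. In the control ventral library the miR-9 rows made up 44.4% of the reads as deposited and 21.2% after merging. Columns of per-sample values that were not used number 8, the RPM columns of the other tables. Reads of miRNAs with near-identical sequences, such as the let-7 and miR-30 families, could have been split between rows by the authors' counting, so the values of single members are uncertain.

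After merging, the libraries held 13839534 (control ventral), 12100970 (control dorsal), 12299682 (iron ventral) and 11396800 (iron dorsal) annotated miRNA reads. A count of 3 reads, the upper limit that a count of 0 allows, equals 0.217 to 0.263 CPM of these totals, before TMM scaling. Libraries were scaled with TMM (edgeR 4.0.16) and expressed as CPM, reads scaled to a common library size. A miRNA was measured if it reached 10 CPM in at least 1 library, which 251 did. For each of 4 pairwise comparisons the ratio of CPM values was given with its exact conditional binomial (Clopper-Pearson) 95% interval, and a miRNA was counted when its ratio was at least 2-fold and the interval excluded 1. These intervals, like those of shares, cover counting error only. They compare libraries, not conditions, and amplified reads are not independent molecules. On simulated Poisson counts for iron against control in ventral hippocampus (251 miRNAs, 60 of them changed 3-fold), the intervals held the true ratio in 94.8% of cases.

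The iron and the region difference over all 4 libraries were tested with edgeR's quasi-likelihood test in an additive model of region and treatment, with Benjamini-Hochberg adjustment and a threshold of 0.05. This model leaves 1 residual degree of freedom. Both regions come from the same pools of piglets, so the p-values describe the spread between these libraries, not between piglets, and are too small for the iron difference. The test was checked on simulated counts with 60 changed miRNAs, fewer than the usual number because only 251 were measured. For the iron difference (a median of 250 miRNAs tested) it recovered 81.5% of 2-fold and 100% of 4-fold changes with 1.0 false calls per simulation. For the region difference (a median of 251) it recovered 71.9% of 2-fold and 100% of 4-fold changes with 1.5 false calls. The simulated libraries were independent, and all miRNAs had the same spread between them. These rates therefore need not hold for the real libraries, and 0 calls there do not exclude changes of these sizes.

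Before the data were examined, 19 miRNA lists were fixed: neuron-enriched, activity-regulated, oligodendrocyte, astrocyte, immune and microglia, erythroid, vascular, choroid plexus, epithelial, ciliated ependymal, muscle, liver, caudal Hox cluster, oxidative stress, iron handling, p53-responsive, let-7, the miR-17 cluster with its paralogs, and the imprinted DLK1-DIO3 locus. Some miRNAs stand in more than 1 list. Each list's median log2 ratio was placed among 10000 random lists of the same size, matched on deciles of mean expression. The percentile describes these libraries and is not a test. The rule for naming miRNAs, also fixed then, took up to 10 highest and 10 lowest counted ratios per comparison, miRNAs called by edgeR, miRNAs at least 2-fold different by iron in both regions, the 5 most abundant per library and the 4 most abundant measured members of each list. Of the conserved and predicted tables it took up to the 3 most abundant entries and the 3 highest and 3 lowest ratios per comparison. Conserved sequences were summed to 278 families, of which 188 reached 10 CPM after TMM scaling of their own. Predicted miRNAs were scaled with the factors of the annotated table, and 112 reached 10 CPM. Alternatives were total count scaling, DESeq2 size factors, the authors' RPM, a minimum of 100 CPM or none, rows not merged, fold thresholds of 1.5 and 4, the DESeq2 Wald test, limma-trend with a prior count of 2, and a model without the other factor. Relative to TMM, total count scaling shifted every dorsal iron ratio by -0.13 on the log2 scale, every ventral one by -0.06, and the region ratios by -0.04 in control and -0.10 in iron piglets. Analyses used R 4.3.3, DESeq2 1.42.0, limma 3.58.1 and Python 3.11.15 with scipy 1.17.1. No genome sequence was used, and no coordinates are given.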

Results

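The study profiled miRNAs in the ventral and dorsal hippocampus of newborn piglets that had received iron dextran to induce oxidative stress, and of untreated littermates. There was 1 pooled library for each of the 4 combinations, with 11396800 to 13839534 annotated miRNA reads per library. Since no combination had a replicate, all ratios below compare libraries and carry counting error only. Of 321 annotated miRNAs, 251 reached 10 CPM in at least 1 library. Across them the libraries correlated at Pearson's r of 0.989 to 0.997 on the log scale, with miRNAs as the units and not independent replicates.

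A few miRNAs dominated every library. The neuronal miR-9 was first in each, with 21.2% of annotated reads in the control ventral library (exact binomial 95% interval 21.2% to 21.2%), 18.01% in control dorsal, 18.5% in iron ventral and 16.8% in iron dorsal. It was followed in each library by miR-99a, at 9.94% to 12.3%, and miR-30e-5p, at 5.16% to 6.70%. The neuronal miR-124a was among the first 5 except in iron dorsal, and miR-7 among the first 5 except in iron ventral. In iron ventral miR-100 took the fifth place, and in iron dorsal miR-30a-5p did. The first 10 miRNAs held 60.2%, 57.1%, 58.1% and 59.7% of reads in control ventral, control dorsal, iron ventral and iron dorsal.

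Iron against control in the ventral hippocampus asks how the miRNAs of this region differ after the iron injections. Of 251 miRNAs, 1 was at least 2-fold higher and 4 were at least 2-fold lower in the iron library. miR-146b, known as a brake on inflammatory signalling, stood at 875 CPM against 380.2 CPM in control, a ratio of 2.30 (95% counting interval 2.23 to 2.38). The mir-146 family, summed from the conserved table, did not reach 2-fold here, though it did for control dorsal against control ventral. The miR-183 cluster, known from sensory epithelia, was lower: miR-183 by 8.01-fold (6.93 to 9.31), from 131 to 16.3 CPM, miR-96-5p by 7.44-fold (6.33 to 8.79) and miR-182 by 2.28-fold (2.13 to 2.44). miR-452 was 3.56-fold lower (2.91 to 4.38). The control ventral library also differed at least 2-fold from control dorsal in miR-146b, miR-183, miR-96-5p and miR-452, and by 1.91-fold (1.80 to 2.04) in miR-182. The epithelial mir-8 family, summed from the conserved table, was also 8.90-fold lower in the iron library (7.71 to 10.3).

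**Figure D1:**
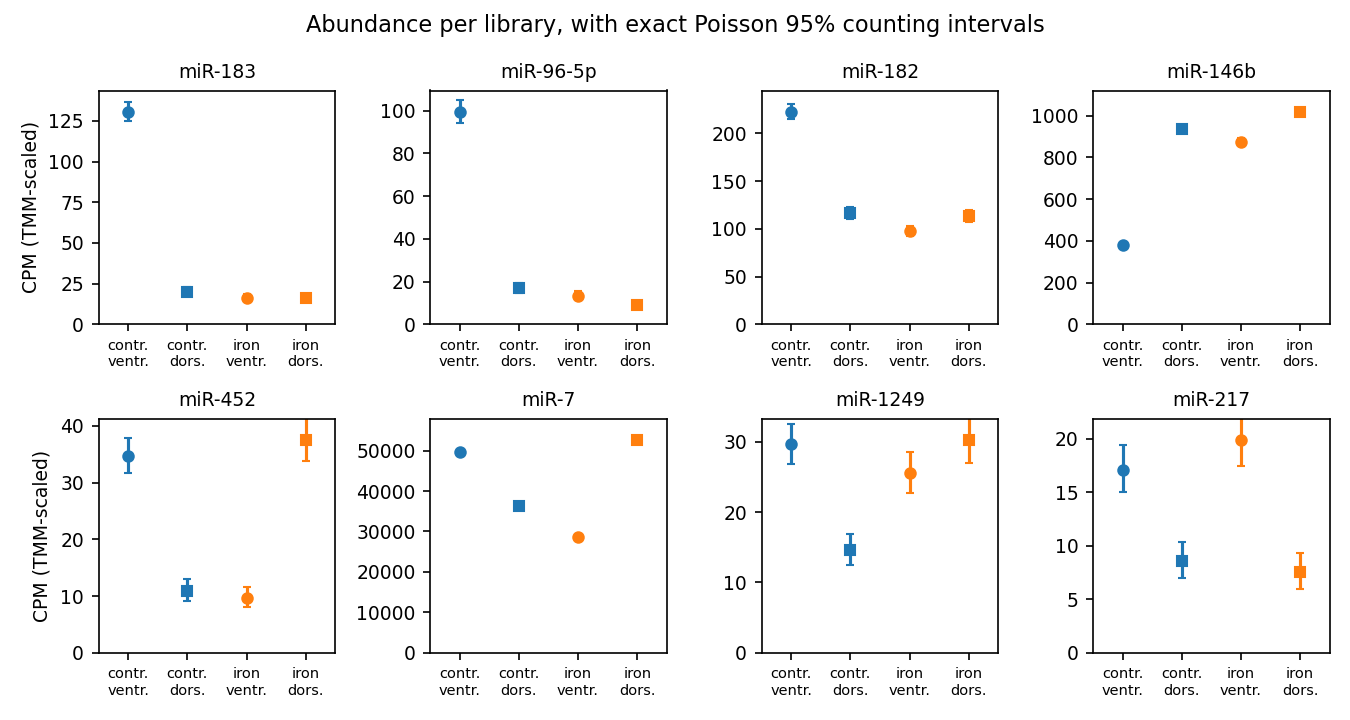
Abundance of 8 miRNAs in the 4 pooled libraries, in TMM-scaled CPM on linear axes from 0; blue is control, orange iron, circles ventral and squares dorsal, and bars are exact Poisson 95% counting intervals. miR-183 stood at 131 CPM in control ventral and at 16.1 to 20.1 CPM in the other libraries, while miR-452 was high in control ventral and iron dorsal.

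Among the lists in ventral hippocampus, liver and muscle lay above the central 95% of random lists. The liver list had 2 measured members, miR-192 at a ratio of 1.54 (1.40 to 1.696) and miR-194a at 1.43 (1.29 to 1.59), with a median log2 ratio of 0.57 at percentile 99.8. The muscle list had a median of 0.33 at percentile 99.5, with 4 of 4 measured members above 1: miR-1 had a log2 ratio of 0.67, miR-133a-3p 0.37, miR-206 0.28 and miR-499-5p 0.11. The list has 8 annotated members. Of those below the minimum, miR-133a-5p was at least 2-fold higher and miR-208b at least 2-fold lower without a filter. Neither list stayed above with a minimum of 100 CPM: liver had 0 measured members, muscle 2 with a percentile of 96.0. Lists closest to the treatment stayed inside that range, but a median would miss members that moved in opposite directions. The oxidative stress list had a median of -0.07 at percentile 12.5, with 5 members above and 6 below 1. Of its abundant members, miR-335 was at -0.69, miR-153 at -0.55, miR-27a at 0.32 and miR-21 at 0.02. The iron handling list had a median of 0.02 at percentile 66.7, with 8 members above and 8 below 1, and log2 ratios of 0.27 for miR-148a-3p, 0.26 for miR-20a, 0.05 for miR-152 and -0.01 for miR-758. Its members ranged from -1.19 for miR-182, counted above, to 0.52 for miR-194a. The p53-responsive list was at 0.23 and percentile 96.4, a value that became -0.02 with a minimum of 100 CPM. The neuron-enriched list was at -0.01 with a mean of -0.17, including miR-7 at -0.79 and miR-128 at 0.35. The oligodendrocyte list was at 0.43 and percentile 94.8, with miR-219b-3p at 0.44 and miR-338 at 0.41. The immune and microglia list had a median of -0.27 but a mean of -0.03, since miR-146b went against miR-146a-5p (-0.42), miR-150 (-0.38) and miR-142-5p (-0.16).

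Iron against control in the dorsal hippocampus asks the same of the other region. Here 2 miRNAs were at least 2-fold higher and 0 lower in the iron library. miR-452 was higher, at a ratio of 3.43 (2.81 to 4.19), from 10.9 to 37.5 CPM. miR-1249 had a ratio of 2.07 (1.72 to 2.502), from 14.6 to 30.2 CPM. miR-192 was just under the threshold, at 1.98 (1.79 to 2.19), and miR-194a was at 1.68 (1.4995 to 1.88). With rows not merged miR-192 was counted too, so 3 were higher and 0 lower. The split depended on scaling: with total counts 1 was higher and 3 were lower, with the authors' RPM 1 was higher and 2 were lower. With a minimum of 100 CPM the count was 0.

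The liver list again lay above the random range in dorsal hippocampus, with a median of 0.87 at percentile 99.8. In both regions the random lists can include this pair itself. Its 2 members are known to be transcribed together, so they are not 2 independent miRNAs as in a random pair. The ciliated ependymal list has miR-34c as its 1 measured member, lower by 1.65-fold (1.63 to 1.67); at percentile 1.9 it lay on the lower end of the random range, since draws of 1 miRNA include miR-34c itself. The oxidative stress list had a median of -0.10 at percentile 18.2, with miR-21 at 0.49, miR-27a at -0.33, miR-335 at -0.10 and miR-153 at 0.02. The iron handling list had a median of 0.10 at percentile 91.3, with 10 members above and 6 below 1, and log2 ratios of 0.63 for miR-758, 0.06 for miR-20a, -0.02 for miR-152 and -0.06 for miR-148a-3p. The p53-responsive list was at 0.18 and percentile 95.3, with miR-192 at 0.99 and miR-194a at 0.75, which it shares with the liver list, miR-145-5p at 0.29, miR-145-3p at 0.07, miR-34a at -0.05 and miR-34c at -0.72. Of its members below the minimum, miR-215 was at least 2-fold higher without a filter. The miR-17 cluster list was at -0.11 and percentile 20.4, although miR-363 was at 0.75 and miR-19b at -0.45, while miR-17-5p was at -0.11 and miR-92b-3p at -0.01. The neuron-enriched list was at -0.17 and percentile 3.4, with miR-7 at 0.53, miR-128 at -0.44 and miR-124a at -0.27. The oligodendrocyte list was at -0.33, the muscle list at -0.28 and the imprinted list at -0.17, each inside the range of random lists. The activity-regulated pair was at -0.21, with miR-212 at -0.37 and miR-132 at -0.05. With total count scaling, which lowers all dorsal iron ratios, log2 values between 0 and 0.13 turn negative.

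Over both regions together, edgeR's quasi-likelihood test of iron against control called 0 of 251 miRNAs at an adjusted p under 0.05, 11 had an unadjusted p under 0.05 where 12.6 are expected by chance, limma-trend called 0, and the DESeq2 Wald test called 1, miR-96-5p, as lower. The smallest adjusted p in edgeR was 0.316, for miR-96-5p, at a log2 difference of -1.95 with 2 of 2 regions lower. miR-34c followed at -0.57 and miR-192 at 0.80, with an adjusted p of 0.713 each in edgeR. With total count scaling, DESeq2 size factors or no filter, edgeR called miR-96-5p and miR-183 as lower, and without a filter miR-429 too; these calls came with an infinite prior degrees of freedom in place of 8.83. Most of the difference of both miRNAs lay in the control ventral library.

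The iron differences of the 2 regions had little in common. Across 251 miRNAs their log2 ratios correlated at Pearson's r of 0.04 and Spearman's rho of 0.05, and 48.6% of them had the same sign. With TMM scaling 0 miRNAs were at least 2-fold different in the same direction in both regions; with total count scaling or the authors' RPM 1 was, miR-96-5p, as lower. In opposite directions there was 1, miR-452, where independent lists would share 0.03. The dorsal log2 ratio exceeded the ventral one by at least 1 for 9 miRNAs and fell short of it by at least 1 for 2; this difference has no residual degree of freedom and was not tested. It was 3.61 for miR-452, 2.68 for miR-183, 1.98 for miR-96-5p, 1.27 for miR-1249, 1.15 for miR-182 and -1.08 for miR-146b. Among the lists the dorsal minus ventral difference of medians was -0.75 for oligodendrocyte, -0.60 for muscle, -0.47 for the caudal Hox cluster and 0.29 for liver.

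**Figure D2:**
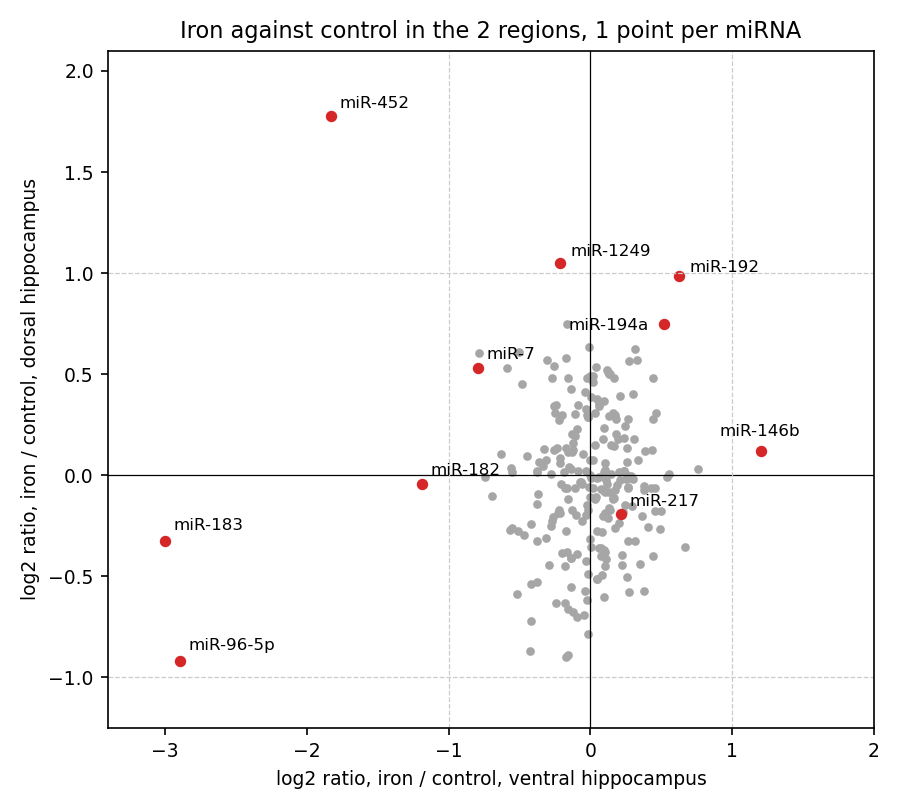
Log2 ratio of iron to control in ventral (x axis) and dorsal hippocampus (y axis) for 251 miRNAs, 1 point each, with dashed lines at 2-fold; red points mark miRNAs counted in any of the 4 comparisons, and miR-7, miR-192 and miR-194a. The cloud has no slope (Pearson's r of 0.04), and miR-452 lies at -1.83 and 1.78.

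Dorsal against ventral in control piglets asks how the regions differ without treatment. In the dorsal library 1 miRNA was at least 2-fold higher and 4 were at least 2-fold lower. miR-146b was higher, at a ratio of 2.46 (2.39 to 2.55). miR-183 was lower by 6.50-fold (5.69 to 7.45), miR-96-5p by 5.90-fold (5.10 to 6.86), miR-452 by 3.17-fold (2.61 to 3.86) and miR-1249 by 2.03-fold (1.71 to 2.43). With the authors' RPM miR-1249 was not counted. Total count scaling added miR-217 as lower, and rows not merged added miR-182 and miR-217. The mir-8 family was 8.20-fold lower (7.14 to 9.45). This comparison and that of iron in ventral hippocampus share the control ventral library, so their ratios are not independent. The imprinted DLK1-DIO3 list lay high, with a median of 0.21 at percentile 99.7 and 10 of 15 members above 1, including miR-127 at 0.43 and miR-323 at 0.39, while miR-370 was at -0.11. Its members share a locus, so they need not be independent as those of a random list are. The muscle list was at 0.35 and percentile 99.1, with miR-1 at 0.84. Of its members below the minimum, miR-208b and miR-499-3p were at least 2-fold lower without a filter. The ciliated ependymal miR-34c was at -0.45 and percentile 1.9. The vascular list was at 0.23 and percentile 95.1 with 6 of 6 members above 1, among them miR-143-3p at 0.61, miR-126-5p at 0.26, miR-126-3p at 0.16 and miR-145-5p at 0.06. Its members are both arms of miR-126, miR-143 and miR-145, so they are not independent either. The caudal Hox pair of miR-10b (0.30) and miR-10a-5p (0.45) had a median of 0.37 at percentile 97.2.

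Dorsal against ventral in iron piglets asks the same after treatment. In the dorsal library miR-452 was higher, at a ratio of 3.85 (3.13 to 4.76), and miR-217 was lower by 2.64-fold (2.05 to 3.45), from 19.9 to 7.51 CPM; these were the 2 miRNAs counted. With total count scaling 1 was higher and 2 were lower, and with a minimum of 100 CPM the count was 0. The oligodendrocyte list had the lowest percentile among the lists, 0.1, with a median of -0.65; miR-219b-3p was lower by 1.58-fold (1.57 to 1.59) and miR-338 by 1.56-fold (1.52 to 1.60). In control piglets the same list was at 0.10, and the difference between the treatments was not tested. The erythroid list was at -0.46 and percentile 2.2, with miR-486 at -0.51, miR-144 at -0.46 and miR-451 at -0.10. The ciliated ependymal miR-34c was at -0.74 and percentile 1.9. The let-7 list had 9 of 9 members above 1 with TMM scaling and a median of 0.13 at percentile 75.1, among them let-7g at 0.39, let-7f at 0.19, let-7a at 0.13 and let-7c at 0.02. With total count scaling, log2 values here between 0 and 0.10 turn negative, let-7c among them. The astrocyte list was at 0.14 and percentile 80.03, with miR-29a at 0.27, miR-23a at 0.22, miR-23b at 0.15 and miR-26a at 0.13. The choroid plexus marker miR-204 was at -0.11 and percentile 45.3.

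**Figure D3:**
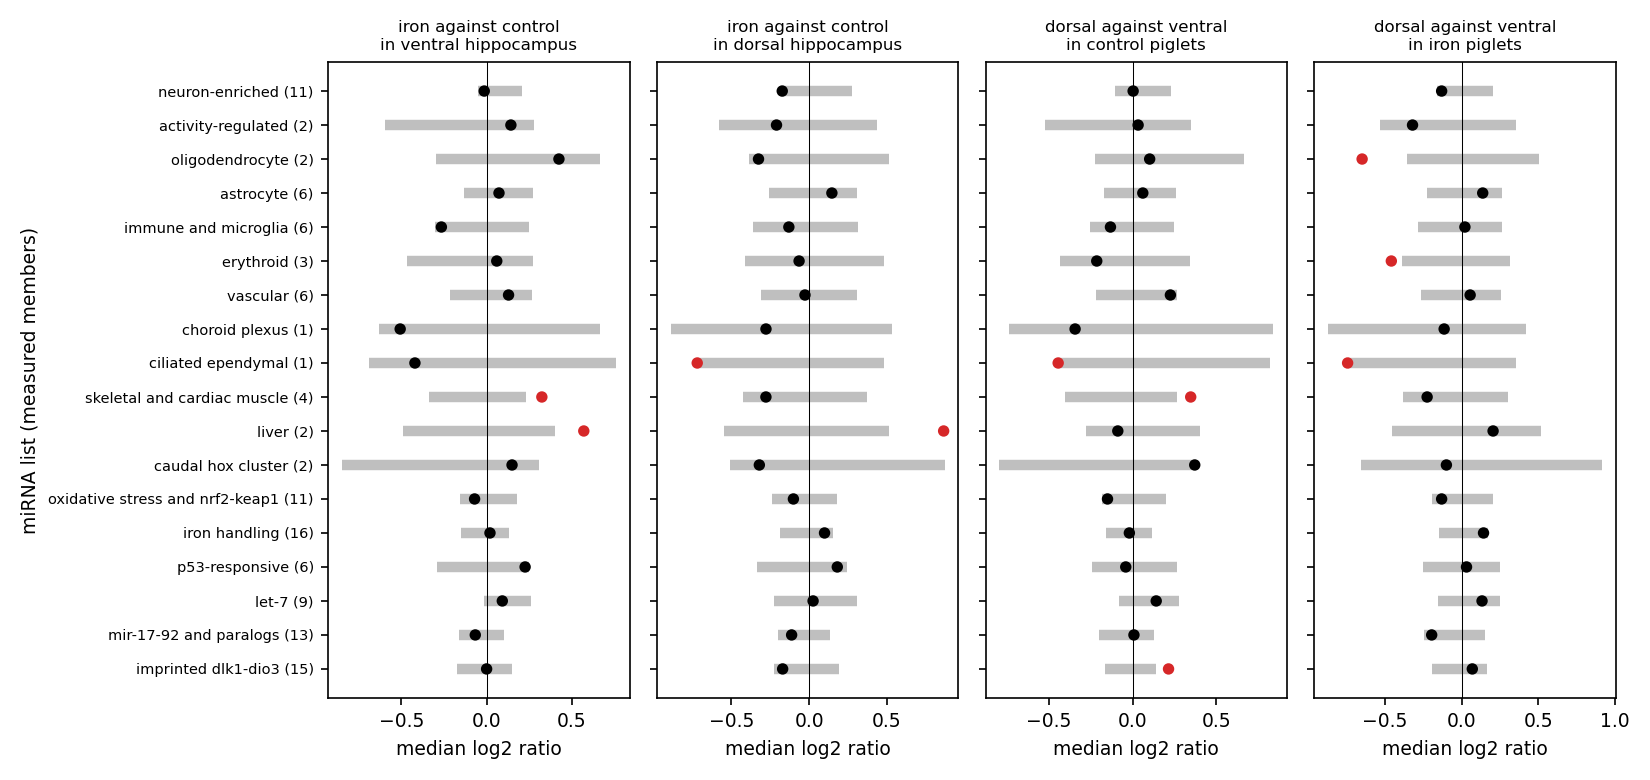
Median log2 ratio of each miRNA list (points) in the 4 comparisons, with the central 95% of 10000 expression-matched random lists as grey bars and the number of measured members in parentheses; red points have a percentile under 2.5 or over 97.5. Of 72 medians 10 are red, where random lists would give 3.6 on average. Of the 10, 7 lie beyond the bars, and the 3 of the 1-member ciliated ependymal list lie on the bar ends. The medians are not independent, since lists share miRNAs and comparisons share libraries. Members of some lists share a locus or a precursor, unlike those of most random lists.

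Dorsal against ventral over both treatments, with the treatment as a term, gave 0 calls among 251 miRNAs with edgeR's quasi-likelihood test. Of these 8 had an unadjusted p under 0.05, and the DESeq2 Wald test and limma-trend called 0. The smallest adjusted p in edgeR was 0.206 for miR-217, at a log2 difference of -1.19 with 2 of 2 treatments lower in dorsal. edgeR called miR-217, miR-96-5p and miR-183 as lower with total count scaling or DESeq2 size factors, again with an infinite prior. The region differences of the 2 treatments correlated at Pearson's r of -0.05 and Spearman's rho of -0.08 across miRNAs, and 117 (46.6%) had the same sign. miR-452 was at least 2-fold different in opposite directions, and 0 were in the same direction with TMM scaling; with total count scaling 1 was, miR-217, as lower in dorsal.

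The table of conserved sequences was led by the families mir-9, mir-10 and mir-30. Beyond families already named, it showed lower values in the iron dorsal library. Against control dorsal, mir-1271 was lower by 3.29-fold (2.91 to 3.72), mir-375 by 2.37-fold (2.13 to 2.65) and mir-216 by 2.32-fold (1.82 to 2.99). Against iron ventral, mir-1271 was lower by 5.61-fold (4.99 to 6.31), mir-216 by 3.57-fold (2.83 to 4.55) and mir-217 by 2.75-fold (2.07 to 3.68). Of the families at 10 CPM or more, 0 were at least 2-fold higher and 5 lower in the ventral iron comparison, 2 higher and 3 lower in the dorsal one. Dorsal against ventral, 1 was higher and 4 were lower in control piglets, and 1 was higher and 8 were lower in iron piglets. Among predicted miRNAs, number 467 had the highest mean CPM, at 19798 in control ventral, 14145 in control dorsal, 16159 in iron ventral and 23396 in iron dorsal. Predicted miRNA 43 followed the miR-183 cluster: it was 13.9-fold lower (10.04 to 19.7) in iron than in control ventral. Numbers 333 and 419 were 6.90-fold (4.27 to 11.8) and 6.41-fold (4.47 to 9.45) lower in the same comparison. The control ventral library stood apart here too. Against it, control dorsal was 13.9-fold lower in number 43, 4.86-fold in 333 and 7.52-fold in 419. In dorsal hippocampus 4 of 112 were at least 2-fold higher and 4 lower in iron. The highest ratios were 2.40 (1.85 to 3.13) for number 489, 2.37 (1.89 to 2.97) for 389 and 2.11 (1.55 to 2.89) for 639. Number 419 was lower by 3.13-fold (1.40 to 7.92), 318 by 2.48-fold (2.24 to 2.75) and the star of 5 by 2.14-fold (2.01 to 2.28). The ratio of number 419 rests on 8 reads in iron dorsal against 29 in control dorsal. That miRNA, like numbers 43 and 333, reached 10 CPM in control ventral alone.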

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

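The exchange of labels below was tested, and pool variation considered, only after the result was seen; the GC content test was set out before. In 7 measured miRNAs the iron ratio went opposite ways in the 2 regions, with both counting intervals excluding 1 and the log2 ratios at least 1 apart. Of these miR-708-5p, miR-7857-3p and miR-582 fall outside the naming rule and were chosen after their values were seen. Whether the regions differed was not tested, since each ratio rests on 1 pool per group. The dorsal minus ventral difference was 3.61 for miR-452, 1.39 for miR-7857-3p, 1.33 for miR-7, 1.27 for miR-1249, 1.12 for miR-708-5p, 1.11 for miR-582 and -1.02 for miR-1. The abundant miR-7 stood at 49733 CPM in control ventral, 36339 in control dorsal, 28702 in iron ventral and 52574 in iron dorsal, so depth does not limit it.

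A linear trend on GC content does not account for these: after its removal over 246 miRNAs with a sequence, the 7 kept a median of 101% of their difference. That trend was shallow, at 0.0042 on the log2 scale per percent of GC, and other forms of sequence bias were not tested. An exchange of the ventral and dorsal labels in 1 treatment group would turn a shared region difference around, but the region differences of the 2 treatments correlated at -0.048, near 0 in either orientation, so an exchange cannot be told apart from correct labels. Variation between pools unrelated to iron and region cannot be told apart from a difference between the regions either, since there was 1 library per combination of region and treatment. A response to iron that differs between the regions stays open, untested.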

How the results depend on the processing

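All ratios rest on 1 pool each, and leaving out any library leaves the additive models without a residual degree of freedom, so those fits were not run. No paired analysis was possible by replicate number because the groups share just 1 number; the region test pairs the regions by pool through its treatment term, and without that term it also made 0 calls. Counts of miRNAs followed the thresholds. For iron in ventral hippocampus the count of 5 became 3 with a minimum of 100 CPM, 9 without one, 14 at 1.5-fold and 2 at 4-fold. For iron in dorsal hippocampus the count of 2 became 4 with total count scaling, 0 with 100 CPM, 6 without a filter, 24 at 1.5-fold and 0 at 4-fold. Dorsal against ventral in control piglets, 5 became 2, 11, 17 and 2 in the same order of filters and folds. In iron piglets, 2 became 0, 4, 21 and 0. The iron test over both regions went from 0 calls to 1 with the DESeq2 Wald test, 2 with total count scaling, 2 with DESeq2 size factors in edgeR and 3 without a filter. The region test went from 0 to 3, 3 and 4 in the last 3 of these. The edgeR settings that made calls are those with an infinite prior degrees of freedom; edgeR settings without calls had 3.92 to 8.83. Differences of the iron effect of at least 1 went from 11 to 7 with 100 CPM, and list medians with a percentile outside the central 95% from 10 to 5 (those beyond the random range from 7 to 5); fewer miRNAs enter both. Of the 5, oligodendrocyte in iron piglets and muscle in control piglets were among the 10, while neuron-enriched in iron piglets, erythroid in control piglets and oligodendrocyte for iron in ventral hippocampus were not. Of the others of the 10, liver had 0 members left, and the percentile was 96.0 for muscle in ventral hippocampus, 92.5 for the imprinted list in control piglets, 4.57 for erythroid in iron piglets and 2.6 for ciliated ependymal in 3 comparisons. The share of the first 10 miRNAs, a mean of 58.8% over the libraries, was 56.9% when predicted reads were added to the total. Both correlations stayed inside their bootstrap intervals (-0.20 to 0.25 and -0.27 to 0.17) in the settings tried. Scaling shifts all log2 ratios of a comparison alike and cannot change Pearson's r. Just the settings that changed which miRNAs entered could move it.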

Other observations

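The tests in this part were chosen after the result was seen, except that on miR-122. The SD over miRNAs of the log2 contrast was 0.283 for iron against control, 0.258 for dorsal against ventral and 0.271 for the crossed contrast of control ventral and iron dorsal with the others, with 7, 7 and 6 miRNAs at least 1.5-fold apart. The crossed contrast also carries any difference of the iron effect between regions, so it does not measure pool variation apart from that. The closest pair was control dorsal with iron ventral, at Pearson's r of 0.997, and these share neither region nor treatment. Control ventral and iron dorsal stood farthest from the mean of the 4, with an SD of 0.295 and 0.263.

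The control ventral library alone was high in the miR-183 cluster. Counting error of independent reads alone is too small for this: the smallest lower counting bound of its ratio to control dorsal among miR-183, miR-96-5p and miR-182 was 1.80. These miRNAs were chosen from the same counts, and the bound leaves out amplification. Noise beyond counting is therefore not excluded. A candidate explanation is epithelial cells or tissue in that pool. The epithelial list fixed before the data were examined had 1 annotated member, miR-429, below the minimum with 65 reads against 3, 3 and 2 in control dorsal, iron dorsal and iron ventral. The mir-8 family of the conserved table, which holds this list, stood at 151 CPM and was 8.20 times as high as in the highest other library, as that explanation needs. An iron effect limited to ventral hippocampus would look the same, and with 1 control ventral library it cannot be told apart.

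miR-192 and miR-194a, known to be transcribed together, were higher in iron in both regions. The erythroid list had a median log2 iron ratio of -0.0021 over both regions. Its 3 members went both ways, from -0.18 to 0.17 in ventral and from -0.26 to 0.34 in dorsal hippocampus. No shared rise of red blood cell miRNAs was seen, which argues against more red blood cells in both iron pools. The list does not cover other blood cells. For liver-type RNA, the test on miR-122 went different ways in the regions. In dorsal hippocampus its iron ratio had an upper counting bound of 1.41, under the 1.68 of miR-194a. By counting error alone this argues against liver-type RNA there, but noise beyond counting is not excluded. In ventral hippocampus the ratio of miR-122 was 1.41 (1.002 to 1.98), close to the 1.43 of miR-194a, so that region does not decide. miR-122 lay below the minimum of 10 CPM, with 83 against 93 reads in dorsal and 79 against 66 in ventral hippocampus, iron first. For p53-driven transcription, the other measured p53-list members had a median log2 iron ratio of 0.0288 and went both ways. Below the minimum, miR-215 of that list was at least 2-fold higher in dorsal but not in ventral hippocampus without a filter. This explanation cannot be told apart. An effect of iron stays open, untested across piglets.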
